A study of Homo sapiens with 9 samples.

How the data were processed

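The series comprised 9 samples of human donor heart left ventricle. There were 4 MR CUT&RUN samples and 4 IgG CUT&RUN samples, 1 of each per combination of storage solution (HTK or HTK+CAN) and time (baseline or 10 h), and 1 single-nucleus RNA sample. The labels do not spell out CAN, and give no storage time for baseline. Groups were taken from the sample titles, and with 1 library per group no test or p-value between groups was made. Per the labels' protocols, nuclei for CUT&RUN were fixed in 0.1% formaldehyde for 1 minute, the assay used an EpiCypher kit and libraries an NEB Ultra II kit. The RNA libraries followed the 10x Chromium protocol for fixed RNA, which counts probes on fixed transcripts and not the transcripts' own sequence.

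Per the submitters' processing notes, Trimmomatic, MACS3, Cell Ranger 7 and GRCh38 were used. The aligner, duplicate handling, peak threshold and sequencing depth of the CUT&RUN libraries are not given in the sources used here. The deposited peak lists are in the narrowPeak layout, 1 list per sample. For each peak they give a score (in these files the whole part of 10 times the -log10 q), the authors' fold enrichment at the summit over the caller's background, and -log10 of the p-value and of the q-value. They also give the authors' summit position. The lowest -log10 q was between 1.31 and 1.32 in every list. The peak names of both HTK lists name an IgG comparison, and those of both HTK+CAN lists do not say which control was used, which could alter the number and place of peaks between solutions. The authors' peak values were used to describe, rank or filter peaks within a list, at the same -log10 q threshold or fold threshold in each list. The fragments and backgrounds recovered from them, as described below, were also set side by side between lists. The deposited single-nucleus matrix holds whole UMI counts per probed gene and nucleus, filtered by the authors to called nuclei, in 15 barcode sets that no source used here ties to a heart or group.

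Peak coordinates were read in GRCh38 and printed from 1. Peaks were shared if they overlapped by at least 1 bp. Each share has a 95% exact (Clopper-Pearson) binomial interval and was set beside 100 random placings of the peaks on their own chromosomes. Gene positions came from a RefSeq table of GRCh38.p14 that gives the lower and higher coordinate of each gene without strand or exons. The planned share at start sites was therefore replaced by the share of summits within 1 kb of either end of a protein-coding gene on chromosomes 1 to 22 and X (19974 genes). Gene interiors and sequence outside protein-coding genes were counted apart. A peak between neighbouring genes counts for each. The planned search for hormone response elements needs a genome sequence and was not run. The fragments at each summit and the caller's background were recovered from the fold and p-value of each peak as whole numbers (to within 0.005 in -log10 p), with a common scale factor of 0.776 in the HTK+CAN list at 10 h. This succeeded for 99.99% of peaks in HTK at baseline, 100% in HTK at 10 h and in HTK+CAN at baseline, and 77.1% in HTK+CAN at 10 h. The commonest background was 1.27 fragments in HTK at baseline, 1.04 in HTK at 10 h and 0.183 in HTK+CAN at baseline. In HTK+CAN at 10 h a single background of 0.180 fragments was solved from the commonest values and applied to every peak.

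Nuclei were kept with at least 200 genes and at most 10% mitochondrial counts. Of 17163 nuclei, 2 whose barcodes were blank in the files used here, 40 below the gene minimum and 927 above the mitochondrial limit were left out, with 2 nuclei counted under both limits. Scrublet, run per barcode set at an expected rate of 0.06, marked 564 of the remaining 16196 nuclei (3.48%) as doublets, which were removed. The 15632 nuclei analysed had a median of 2204 UMIs and 1405 genes. Before filtering, barcode sets held 324 to 2175 nuclei with median UMI counts from 1187.5 to 3309. Among the nuclei analysed they held 298 to 2109 nuclei with medians from 1128 to 2938. Counts were normalised to 10000 per nucleus and log-transformed. Leiden clustering at resolution 0.5 used 2000 variable genes, 30 principal components and 15 neighbours and gave 20 clusters. Clusters were named from 15 marker lists. The scoring thresholds were set after seeing the data. A list needed a median marker log2 difference of at least 1 over the median of all clusters. At least 3 markers had to be higher and detected in 10% of nuclei. The second-best list had to score below 0.75 of the best. The top 10 genes could not favour another class by 2 or more markers. A cluster with a median UMI count far below that of all nuclei also needed a marker of its own class among them. These rules left 6.72% of nuclei unnamed. UMI counts were summed per class as CPM, with exact Poisson intervals. Of the 18082 gene IDs, 18049 matched the gene name table, and 17930 protein-coding genes were matched to a probed gene.

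The 14 gene lists (corticosteroid targets, steroid receptor axis, inflammation, immediate early, heat shock, hypoxia and glycolysis, mitochondrial and fatty acid, apoptosis and necrosis, fibrosis and matrix, sarcomere, calcium and ion handling, natriuretic and stretch, condensate and coactivator, circadian) and the marker lists were fixed before the data were examined. So were the comparisons, the settings of overlap and clustering and the rule for which genes are named. At peaks, a list's count of genes with a gene-end peak was placed among 10000 random lists of the same size, matched on expression in 10 bins. In the nuclei, the measure was a list's median log2 difference between a class and all other named classes (CPM with a pseudocount of 1). It was placed among 10000 matched random lists. Unnamed nuclei were left out of this comparison. Of 126 pairs of list and class, 26 were in the top 2.5% and 51 in the bottom 2.5%. These percentiles describe these libraries.

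The genes named were chosen by rule. For each peak comparison these were all corticosteroid targets and steroid receptor axis genes with a gene-end peak in either list, and up to 3 members of each other list with the highest authors' fold. The 5 genes per direction with the highest fold at a peak the other list does not overlap were added. For the nuclei they were NR3C2, NR3C1, HSD11B1 and HSD11B2, the top 5 genes by fold per cluster among those detected in at least 25% of its nuclei, and up to 3 members of each list in the class where it stood highest. Further list members with a peak are named where a count is spelled out, chosen after their values were seen. XIST and Y-linked genes were left out everywhere. Some genes that the rule selects are not reported here.

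Alternatives covered the peak threshold, sequences and merging, the definition of a shared peak, the distance to a gene end, the matching of random lists, the filters, resolution and doublet removal of the nuclei, the pseudocount and the unit of receptor levels. Thresholds of -log10 q of 2 and 3 and values within or weighted by barcode sets were added after seeing the data. So were values of lists and named list genes without the 4 named clusters found in few sets. So was a thinning of the HTK baseline summits, in which each recovered fragment is kept with 1 probability and the background is lowered alike or set to the ratio of the 2 lists. Peak numbers over 3 kb from a gene end were also compared only then.

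The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9, and interval overlap was computed in numpy. The steps were tested on simulated data. All 2500 planted shared peaks and all 1457 planted by reciprocal overlap were found, and fragments were recovered at all 2000 simulated summits. The computed share of summits kept after thinning was 93.2%, as in simulated thinning. For 100 genes each of 18066 with a true log2 difference of 1 or 2 between classes, the median estimates were 0.95 and 1.93. Of 10 lists of changed genes 10, and of 200 unchanged lists 5, fell in the top 2.5% of random lists. Clustering placed 99.6% of 1600 simulated nuclei of 4 types with their own type.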

Results

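Nuclei from the left ventricle of human donor hearts were profiled by CUT&RUN, in which an antibody directs the release and sequencing of DNA fragments next to the protein it binds, and by single-nucleus RNA sequencing. The CUT&RUN antibody was directed against the mineralocorticoid receptor (MR, encoded by NR3C2), a nuclear receptor for aldosterone and cortisol. The series title names the receptor's physical phase transition and the preservation of donor hearts, and the groups set storage time and storage solution against each other. Hearts were stored in HTK, a cold preservation solution of histidine, tryptophan and ketoglutarate, or in HTK with an additive labelled CAN, and were sampled at baseline and at 10 h. Each of the 4 groups had 1 MR peak list, so every difference between groups is a difference between 2 libraries with no replicate check. The 4 IgG samples were not analysed here. The peak lists held 10055 peaks in HTK at baseline, 5485 in HTK at 10 h, 66481 in HTK+CAN at baseline and 1809 in HTK+CAN at 10 h. The single-nucleus sample held 17163 nuclei and 18082 probed genes, with a median of 2343 UMIs and 1442 genes per nucleus.

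In HTK, MR peaks lay at the ends of well-known corticosteroid receptor target genes at both times. FKBP5, a co-chaperone of steroid receptors, had a baseline peak on chromosome 6 at 35727257 to 35728413 (GRCh38), just inside the gene's higher-coordinate end, and an overlapping peak at 10 h at 35727523 to 35728277. Overlapping peaks at both times were also found at DUSP1, a MAP kinase phosphatase, at the metallothionein MT1X and at PDK4, an inhibitor of pyruvate dehydrogenase. Peaks at ZBTB16, at the epithelial sodium channel subunit SCNN1A, at NDRG2 and at ADAMTS1 were present at baseline and not at 10 h, whereas peaks at the clock gene PER1 and at ERRFI1 were present at 10 h and not at baseline. In all, 9 of 24 measured corticosteroid targets had a gene-end peak at baseline (percentile 88.1 among random lists of like expression) and 7 of 24 at 10 h (percentile 98.6). At baseline the percentile was 98.9 at 3 kb and 99.5 among lists matched on gene length, so both times stood high there. With length matching, 11 of 14 gene lists were at or above percentile 95 at baseline and 7 of 14 at 10 h, against 2 and 2 with lists of like expression.

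The authors' fold enrichment over the caller's background, which ranks peaks within a list only, was 17.8 for FKBP5, 10.6 for ZBTB16, 9.32 for DUSP1 and 8.35 for SCNN1A in the baseline list. In the 10 h list it was 8.74 for FKBP5, 7.28 for MT1X and 3.30 for PER1. Of the 16 measured genes of the steroid receptor axis, 3 had a gene-end peak at baseline and 2 at 10 h. H6PD, which supplies the cofactor of cortisol regeneration, had overlapping peaks at both times, and the corepressor NCOR1 had one at baseline.

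Immediate early and inflammation genes stood highest among random lists of like expression in HTK at baseline. Of 22 immediate early genes, 13 had a peak at baseline, where random lists had a median of 6 (percentile 99.9), and 7 had one at 10 h, where random lists had a median of 3 (percentile 99.0). FOSL2, JUN, JUNB, JUND, KLF2 and MYC had a peak in both lists. The zinc finger factors KLF4 (14.1-fold enrichment) and EGR1 (12.5-fold) and the AP-1 subunit FOS (9.51-fold) had one at baseline only. Of 24 inflammation genes, 10 had a peak at baseline (percentile 98.1) and 5 at 10 h (percentile 93.8). The cytokine IL6, the NF-kB inhibitor TNFAIP3 and the cytokine signalling inhibitor SOCS3 had overlapping peaks at both times, and NFKBIA had one at baseline only.

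Of 16 heat shock genes, 6 had a gene-end peak in HTK at baseline, among them HSPB7, HSPB1 and HSPA8, where random lists of like expression had a median of 5 (percentile 75.1) and lists matched on gene length a median of 2 (percentile 98.7). At 10 h 0 of 16 had one, where random lists of like expression had a median of 2 (percentile 4.68) and lists matched on gene length a median of 1 (percentile 16.45). The hypoxia and glycolysis list had 6 of 16 members at baseline and 4 of 16 at 10 h, with EPAS1, VEGFA and ADM in both. For mitochondrial and fatty acid genes the counts were 9 and 4 of 20. COXFA4 had a peak at baseline, and 1 shared peak lay between HADHA and HADHB at both times. Apoptosis and necrosis genes had 7 of 20 at baseline, with GADD45A and APAF1, and 5 of 20 at 10 h, with PMAIP1.

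Of the fibrosis and matrix genes, 9 of 24 had a peak at baseline and 3 of 24 at 10 h. SMAD3 had overlapping peaks, whereas TGFBR2 and FN1 had one at baseline only. Sarcomere genes had 6 of 20 at baseline, with TPM1 and CSRP3, and 1 of 20 at 10 h, MYOM1, whose peak also lay at an end of MYL12A. Calcium and ion handling genes had 7 and 3 of 20, with CAMK2D and JPH2 in both lists and CACNB2 at baseline. ANKRD1 was the 1 natriuretic and stretch gene of 12 with a peak in each list, and its 10 h peak overlapped a baseline peak. Condensate and coactivator genes, which encode proteins known to gather in nuclear condensates, had 6 of 12 at baseline, with DDX3X, MED1 and EP300, and 2 of 12 at 10 h, EWSR1 and SON. NPM1, which has no matched probe in the nuclei and is not in that count, had a peak at 10 h. Circadian genes had 6 of 15 at baseline and 4 of 15 at 10 h, with BHLHE40 in both, TEF at baseline and NR1D2 at 10 h. Outside these lists, the gene-end peaks of highest enrichment without a counterpart were at CHD9 (20.2-fold), INO80C, GAREM1 and the pair LRRC41 and UQCRH at baseline. At 10 h they were at NCAPG2 (11.3-fold), SLC17A5, DENR, EMCN and CNIH4.

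The HTK list at 10 h held 0.546 times the peaks of the baseline list and covered 2234879 bp against 4707576 bp. Genes with a gene-end peak numbered 3182 at baseline and 1488 at 10 h, and 986 genes were in both, where lists of these lengths drawn independently would share 237.

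In HTK+CAN, few of the same genes had peaks at either time. PER1 was the 1 corticosteroid target of 24 with a gene-end peak at 10 h, at chromosome 17, 8152226 to 8152755. At baseline 2 of 24 had one, the metallothionein MT2A and PER1, the latter with its strongest gene-end peak at the gene's other end (8140050 to 8140354), resting on 3 fragments at its summit. Of the 16 steroid receptor axis genes, HSD11B2, which inactivates cortisol, H6PD and the coactivator NCOA3 had a peak at baseline, and 0 of 16 had one at 10 h. The HSD11B2 peak also lay at an end of ATP6V0D1.

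Among the other groups in HTK+CAN at baseline, 6 of 20 apoptosis and necrosis genes had a gene-end peak (percentile 98.7). They were led by GADD45B (6.35-fold enrichment), MCL1 (5.80-fold) and GADD45A (4.92-fold), whose peaks rested on 8, 7 and 5 fragments. Heat shock genes had 4 of 16 (percentile 94.8), namely HSPB7, HSPA1A and the pair HSPD1 and HSPE1, which share 1 peak. HSPA1A has a near-identical neighbour, HSPA1B, so its peak may hold fragments of either gene. Inflammation genes had 5 of 24, with CXCL2 and IL6, and immediate early genes 2 of 22, NR4A2 and KLF2. The remaining lists had few members with a peak. LDHB, PPARGC1A, COL1A2, POSTN, TGFB1, NPR1, ACTA1 and CRY2 were among those with a peak, and 0 of 20 sarcomere and 0 of 20 calcium handling genes had one. At 10 h the members with a peak were RELA, NDUFS1, SMAD7, MED1, NR1D1 and PER1. The circadian list, with 2 of 15, stood at percentile 98.7. At each time in HTK+CAN, 1 of 14 gene lists was at or above percentile 95, which 14 random lists could also give.

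The highest gene-end enrichments without a counterpart in HTK+CAN were at LOC107987042 (13.9-fold), INHBC, DBNDD1, LOC124904792 and C1orf185 at baseline. At 10 h they were at STX7 (14.0-fold), LOC124901235, DIAPH3, TEX19 and PDCL. Only 19 genes had a gene-end peak at both times, where independent lists would share 25.6. The peak number at 10 h was 0.0272 times that at baseline, a 36.8-fold difference that was 5.44-fold among peaks with an authors' -log10 q of 5 or more. Of the baseline peaks, 99.6% had 10 or fewer fragments at the summit, with a median of 3, and 1.99% reached a -log10 q of 5.

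At baseline, none of the 9 corticosteroid targets with a gene-end peak in HTK had one in HTK+CAN. Over all genes this share was also low: 393 of the 3182 genes with a gene-end peak in HTK (12.4%) had one in HTK+CAN. The 9 targets of the HTK list, among them FKBP5, ZBTB16, DUSP1, MT1X, SCNN1A, NDRG2, ADAMTS1 and PDK4, had no overlapping HTK+CAN peak, and MT2A and PER1 had one in HTK+CAN alone. The strongest gene-end peaks of H6PD did not overlap a peak of the other list. IL6, GADD45A and the HSPD1 and HSPE1 pair had overlapping peaks in both solutions. KLF4, EGR1, FOS, TNFAIP3, NFKBIA, EPAS1, VEGFA, HADHA, HADHB, COXFA4, SMAD3, TGFBR2, FN1, MYOM1, TPM1, CSRP3, CAMK2D, CACNB2, ATP1B1, ANKRD1, DDX3X, MED1 and BHLHE40 had a peak in HTK with no HTK+CAN peak over it. The strongest HTK peaks of this kind were at AHCYL1 (21.97-fold enrichment), CHD9, MAOA (17.8-fold), FKBP5 and INO80C. The strongest in HTK+CAN were at LOC107987042, USP40 (12.1-fold) and INHBC.

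The HTK+CAN baseline list was 6.61 times as long as the HTK list, but the order was the opposite among stronger peaks: with a -log10 q of 5 or more, 1321 peaks remained in HTK+CAN and 5883 in HTK, a ratio of 0.225. Within 1 kb of a summit the longer list reached fewer genes, 2077 against 3182, of which 393 were in both, where independent lists would share 331. Within 3 kb the order was the opposite among measured genes, with 4568 in HTK+CAN and 3628 in HTK.

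At 10 h, PER1 was the corticosteroid target with a peak in both solutions, and the 2 peaks overlapped (chromosome 17, 8151742 to 8152421 in HTK). FKBP5, DUSP1, MT1X, ERRFI1 and PDK4 had a peak in HTK only, as did H6PD. In the other groups, SOCS3 (13.7-fold enrichment), TNFAIP3, IER3, KLF2, JUNB, VEGFA, ADM, PMAIP1, SMAD3, COL1A2, MYOM1, JPH2, CAMK2D, KCNJ2, ANKRD1, EWSR1 and NR1D2 had a peak in HTK that no HTK+CAN peak overlapped. RELA, SMAD7, MED1 and NR1D1 had one in HTK+CAN alone. NDUFS1, a subunit of respiratory complex I, had a peak in each list, and the strongest ones lay at the same end without overlap. The strongest gene-end peaks of 1 solution were at the pair AUP1 and HTRA2 (15.9-fold), SNX18, SOCS3 and DHX8 in HTK. In HTK+CAN they were at WDR81 (16.0-fold), STX7, LOC124901235, DIAPH3 and TEX19.

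The HTK+CAN list at 10 h held 0.330 times the peaks of the HTK list, and 0.0854 times at a -log10 q of 5 or more. It reached 246 genes against 1488, with 40 in both, where independent lists would share 18.3.

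**Figure D1:**
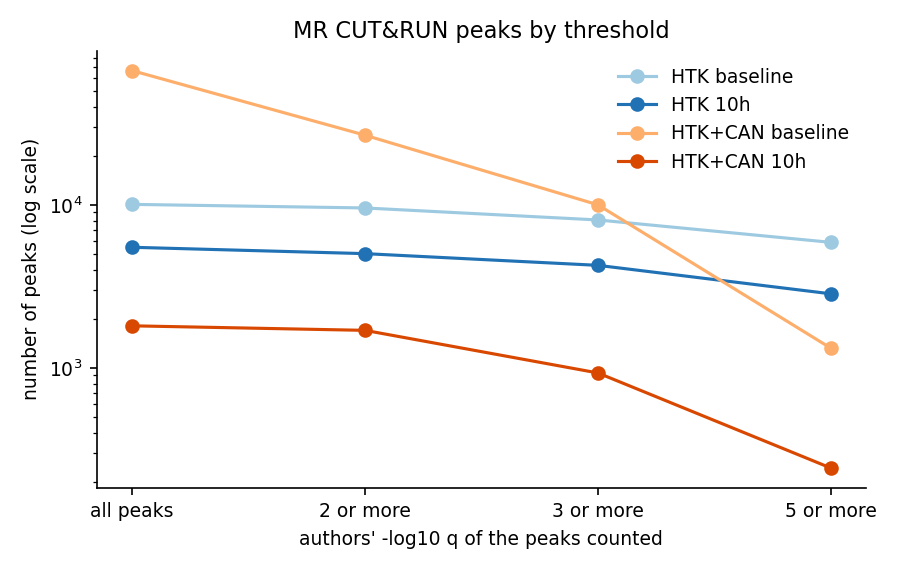
Number of MR CUT&RUN peaks (log axis) in the 4 lists, counted over all peaks and over peaks with an authors' -log10 q of at least 2, 3 or 5. The HTK+CAN baseline line starts highest, at 66481, and ends at 1321, below both HTK lines, while the HTK+CAN 10 h line is the lowest throughout.

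The HTK lists shared peaks with each other far more than with the HTK+CAN lists. Of the HTK peaks at 10 h, 48.5% (95% exact binomial interval 47.2 to 49.9) overlapped a baseline peak, against 0.292% after random placing. The shares were higher among the strongest 10% of peaks: 73.9% of those at 10 h overlapped the baseline list and 68.1% of those at baseline overlapped the 10 h list. Of the HTK baseline peaks, 3.63% (3.27 to 4.01) overlapped the HTK+CAN baseline list, against 1.96% after random placing. Of the HTK+CAN peaks at 10 h, 2.93% (2.20 to 3.81) overlapped their own baseline list, where random placing gave a mean of 1.82% and at most 2.62%. More of them, 5.20%, overlapped the much shorter HTK baseline list, 17.7 times the share after random placing, and 3.04% (2.30 to 3.94) overlapped the HTK list at 10 h. Intervals here and below cover counting error only.

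Peaks in HTK were concentrated at gene ends. The share of peaks with a summit within 1 kb of either end of a protein-coding gene was 27.5% (26.7 to 28.4) in HTK at baseline and 22.9% (21.8 to 24.1) at 10 h. In HTK+CAN it was 2.91% (2.78 to 3.04) at baseline and 10.9% (9.54 to 12.5) at 10 h. Random placing gave between 2.38% and 2.59%, so the observed shares were 10.7, 9.17, 1.23 and 4.37 times those of random positions. Restricted to a -log10 q of 5 or more, the shares were 29.97%, 25.7%, 5.60% and 28.4% in the same order, which places the 243 HTK+CAN peaks at 10 h near both HTK lists. Gene interiors held 35.2%, 27.2%, 42.8% and 40.8% of peaks, and 36.9%, 47.9%, 53.5% and 47.3% lay outside protein-coding genes. The HTK baseline list also had 1 peak over 16291 bp of the mitochondrial genome, its strongest by -log10 q, and the other 3 lists had none there.

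**Figure D2:**
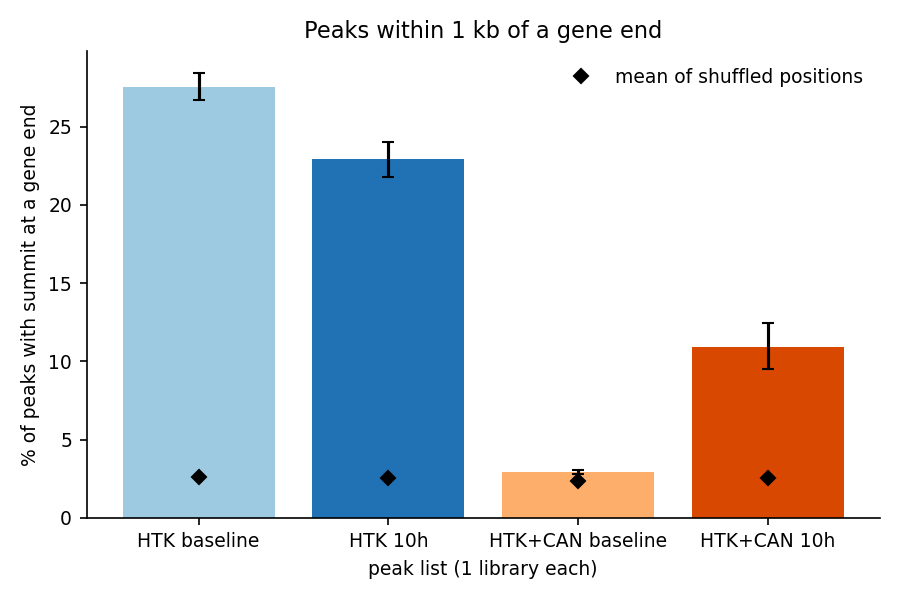
Percent of peaks with the summit within 1 kb of a gene end in each list (bars; 1 library each), with 95% exact binomial intervals, and the mean share of randomly placed peaks (diamonds). HTK at baseline (27.5%) and at 10 h (22.9%) lie far above the diamonds, and HTK+CAN at baseline (2.91%) lies next to its diamond.

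Genes with a gene-end peak were among the more highly expressed genes of the nuclei. Over 17930 protein-coding genes, the median level was 47.8 CPM for genes with an HTK baseline peak and 13.1 CPM for the others, a ratio of 3.66. The ratio was 2.92 in HTK at 10 h (48.1 against 16.4 CPM), 1.22 in HTK+CAN at baseline (22.6 against 18.6) and 1.81 in HTK+CAN at 10 h (34.1 against 18.8). Genes with an HTK baseline peak were highest in endothelial-like nuclei in 11.4% of cases (10.2 to 12.7), against 9.91% of all 11679 genes compared, and in cardiomyocyte-like nuclei in 11.6% against 12.3%. The endothelial-like value was the 1 of 36 pairs of list and class whose interval left out the share of all genes. These are medians and shares across genes, which are not replicates.

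The nuclei comprised the main cell types of the ventricular wall. Of 15632 nuclei analysed, 28.3% (27.6 to 29.0) were cardiomyocyte-like, 23.5% (22.8 to 24.2) endothelial-like, 19.1% (18.5 to 19.7) fibroblast-like and 10.3% (9.86 to 10.8) pericyte-like. Myeloid-like nuclei made up 7.46%, smooth muscle-like nuclei 1.86%, T or NK cell-like nuclei 1.31%, neuronal or glial-like nuclei 1.05% and lymphatic endothelial-like nuclei 0.429%. The cardiomyocyte-like clusters were led by CPLX3 and TNNT1, by NPPA, TCAP and DES, and by MPP3 and CYP2J2. The endothelial-like clusters were led by CA4 and CD300LG, by the adhesion molecule SELE and the growth factor CSF3, and by SELP and ACKR1. A main fibroblast-like cluster was led by ACSM3 and VIT, and another by the cytokine genes LIF and INHBA with PTX3. Pericyte-like clusters were led by AGAP2 and MUC3A, and by MUC3A and ADAMTS4. Myeloid-like clusters were led by FGD2 and SIGLEC1, and by IL1B, TNIP3 and EREG. The other classes were 1 cluster each, led by MYH11 and ITGA8 (smooth muscle), PRF1 and NKG7 (T or NK), L1CAM and SOX10 (glial) and CCL21 and MMRN1 (lymphatic). The remaining 6.72% lay in 4 unnamed clusters, led by FOSB and ATF3, by SGMS2 and KLHL41, by ATP5PO and APOE, and by ADRA2C and ACTA2. No cluster met the naming rule for endocardial, B or plasma, mast, adipocyte, mesothelial or cycling cells. The deposited matrix held 15 barcode sets that no label ties to a heart, a solution or a time, so the nuclei are 1 sample and no share was compared between groups.

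NR3C2 UMIs were found in every class, with the highest pooled CPM in endothelial-like nuclei. Its level was 110 CPM (95% exact Poisson interval 102 to 118) in endothelial-like nuclei, 76.0 CPM (73.3 to 78.7) in cardiomyocyte-like, 71.8 in pericyte-like, 70.8 in fibroblast-like and 52.0 CPM (44.3 to 60.5) in myeloid-like nuclei. The small T or NK cell-like and lymphatic endothelial-like classes had 93.9 and 93.7 CPM, with intervals that overlapped the endothelial one. Endothelial-like nuclei had the higher level in 15 of 15 barcode sets against fibroblast-like and against myeloid-like nuclei, and in 10 of 13 sets against cardiomyocyte-like nuclei. With each set weighted equally, the means were 105 CPM in endothelial-like nuclei (15 sets) and 103 CPM in cardiomyocyte-like nuclei (13 sets). The medians over sets were 93.0 and 68.3 CPM. The size of the difference between these 2 classes therefore rests on how sets are weighted, and by set means they were nearly equal. Set means in fibroblast-like and myeloid-like nuclei were 50.6 and 32.3 CPM, below the intervals of their pooled values. An NR3C2 UMI was seen in 37.2% of cardiomyocyte-like and 16.9% of endothelial-like nuclei, whose median UMI counts were 6618 and 1643. After thinning to 1000 UMIs per nucleus these shares were 7.56% and 10.7%, and 3.36% in myeloid-like nuclei. The small T or NK cell-like and lymphatic endothelial-like classes then had 11.8% (6.88 to 18.4) and 12.5% (4.19 to 26.8). The class of highest NR3C2 level is therefore not settled among these and endothelial-like nuclei.

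NR3C1, the glucocorticoid receptor gene, ranked the classes differently. It was lowest in cardiomyocyte-like nuclei, at 46.0 CPM (44.0 to 48.2), and higher in endothelial-like (90.3 CPM), pericyte-like (110 CPM), myeloid-like (111 CPM) and fibroblast-like nuclei (112 CPM). The small T or NK cell-like, neuronal or glial-like and lymphatic endothelial-like classes had the highest values, at 117, 149 (106 to 205) and 156 CPM (101 to 230). Over all named nuclei together, NR3C2 CPM exceeded NR3C1 CPM in cardiomyocyte-like and endothelial-like nuclei only. With sets weighted equally the endothelial-like means were nearly equal, at 105 CPM and 104 CPM. After thinning, the share of nuclei with a UMI was also higher for NR3C2 than for NR3C1 in 2 small classes. It was 11.8% (6.88 to 18.4) and 8.82% (4.64 to 14.9) of 136 T or NK cell-like nuclei. Of 40 lymphatic endothelial-like nuclei it was 12.5% (4.19 to 26.8) and 10% (2.79 to 23.7). The intervals of each pair overlapped widely, so these shares do not order the 2 genes. HSD11B1, which regenerates cortisol, was found mainly in fibroblast-like nuclei, at 23.3 CPM (20.01 to 26.98), against 4.41 CPM in myeloid-like and 0.321 CPM in cardiomyocyte-like nuclei. HSD11B2 was highest in pericyte-like nuclei, at 31.1 CPM (25.5 to 37.6), with 7.81 CPM in fibroblast-like, 0.321 CPM in cardiomyocyte-like and 0.142 CPM in endothelial-like nuclei. With sets weighted equally, its means were 35.3 CPM in pericyte-like and 18.3 CPM in fibroblast-like nuclei, and the medians over sets 29.4 and 3.77 CPM.

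**Figure D3:**
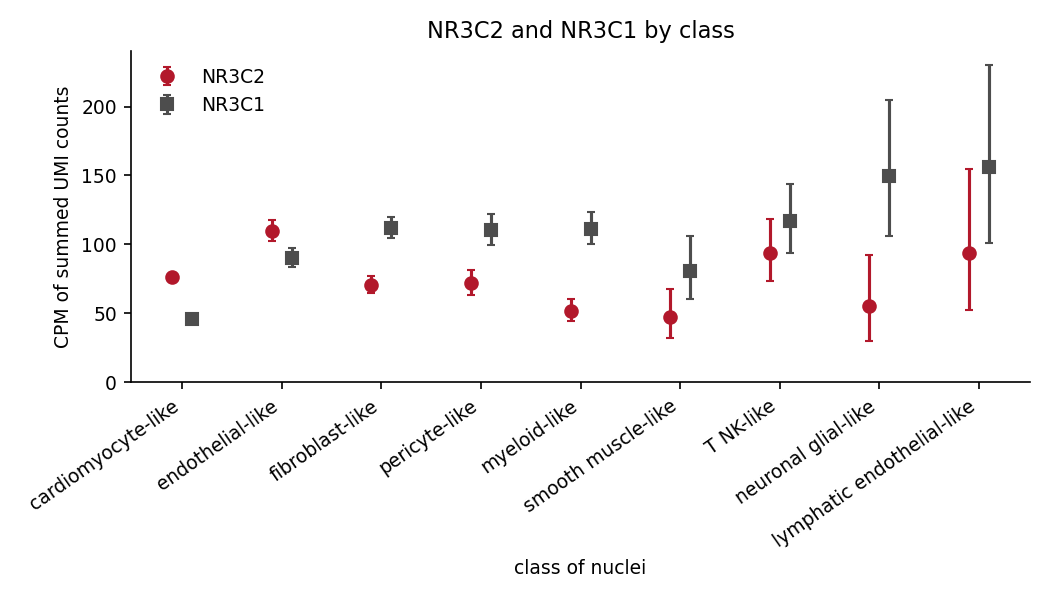
NR3C2 (circles) and NR3C1 (squares) in CPM of summed UMI counts for each class of nuclei, with 95% exact Poisson intervals. NR3C2 lies above NR3C1 in cardiomyocyte-like (76.0 against 46.0 CPM) and endothelial-like nuclei (110 against 90.3 CPM) and below it in the others.

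Contractile, calcium handling and metabolic genes were highest in cardiomyocyte-like nuclei. All 20 sarcomere genes were higher there than in the other classes, with a median log2 difference of 2.83, with MYBPC3 16.2-fold and the giant sarcomere protein gene TTN (14944 CPM) 10.5-fold higher. Calcium and ion handling genes had a median of 2.27 (19 of 20 higher), with the ryanodine receptor RYR2 11.8-fold and JPH2 8.59-fold higher. The median folds of RYR2 and JPH2 within barcode sets were 20.9 and 8.68. Natriuretic and stretch genes had 2.05 (9 of 12 higher), with MYH7, NPPB and NPPA. The markers that named this class include TTN, MYBPC3, RYR2 and MYH7, so high values of these genes there follow partly from the naming. Mitochondrial and fatty acid genes had 1.47 (17 of 20 higher), with PPARGC1A, CPT1B and HADHB. The hypoxia and glycolysis list had a median of 0.32 (12 of 16 higher), with PFKM, LDHB and SLC2A4, and stood at percentile 97.3.

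Over all named nuclei together, corticosteroid targets and inflammation genes had their highest medians in endothelial-like nuclei. Of 24 corticosteroid targets, 17 were higher there, with a median log2 difference of 0.69. They were led by NEDD9 (615 CPM, 33.6-fold), the vasoconstrictor peptide gene EDN1 (121 CPM, 27.2-fold) and the cell cycle inhibitor CDKN1C (18.0-fold). The difference within barcode sets had a median of 0.40 and was above 0 in 14 of 15 sets, and it was 0.44 without 4 clusters found in few sets. The same targets stood at -1.34 in cardiomyocyte-like nuclei, where 7 of 24 were higher. Inflammation genes had a median of 2.18 in endothelial-like nuclei (19 of 24 higher), with the adhesion molecules SELE (101-fold), VCAM1 (28.6-fold) and ICAM1 (15.5-fold). These values include the SELE and CSF3 cluster, which lay almost wholly in 3 of the 15 sets: SELE was at 585 CPM over all endothelial-like nuclei, with a median over sets of 13.7 CPM. The inflammation median within sets was 1.65 in endothelial-like nuclei and 0.40 in myeloid-like nuclei, and without the 4 clusters found in few sets it was 1.70 and 1.74. Apoptosis and necrosis genes had 0.86 in endothelial-like nuclei (16 of 20 higher), led by MLKL (20.1-fold), PMAIP1 (11.4-fold) and RIPK3 (10.6-fold), and 0.76 in myeloid-like nuclei. Without the 4 clusters these folds were 9.93, 2.52 and 11.1, and the SELE fold was 8.25. Within sets the order was the opposite, with 0.36 in endothelial-like and 0.53 in myeloid-like nuclei, whereas without the 4 clusters the medians were 0.85 and 0.79.

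Fibrosis and matrix genes were highest in fibroblast-like nuclei, with a median of 2.57 (23 of 24 higher). COL6A3 (2148 CPM, 59.7-fold), MMP2 (48.6-fold) and the collagen cross-linking enzyme LOX (29.2-fold) were in front. Their median folds within barcode sets were 94.9, 47.3 and 30.6. COL6A3 was also a marker that named this class, so its high value there follows partly from the naming. All 22 immediate early genes were also higher there than in the other named classes, with a median of 2.42, led by EGR2, EGR1 and EGR3. The unnamed cluster led by FOSB and ATF3 was left out, with FOS at 2700 CPM against 215 CPM in all other nuclei. Its best marker lists were cardiomyocyte and myeloid, with scores of 1.98 and 1.91. Within barcode sets the immediate early median in fibroblast-like nuclei was 0.92. Without the 4 clusters found in few sets it was 1.18, below the 1.64 of neuronal or glial-like and the 1.29 of myeloid-like nuclei. EGR2 was then 5.53-fold higher, against 27.2-fold over all named nuclei. Circadian genes had a median of 0.70 (12 of 15 higher), with BHLHE40, NR1D1 and ARNTL, and the steroid receptor axis 0.53 (13 of 16 higher), with HSD11B1, the estrogen receptor ESR1 and the chaperone HSP90AA1. Their medians within sets were 0.52 and 0.22. HSP90AA1 was 3.68-fold higher over all named nuclei and 0.794-fold without the 4 clusters. Condensate and coactivator genes had their highest median, 0.53, in pericyte-like nuclei (11 of 12 higher), where EP300 was 1.88-fold and CCNT1 1.58-fold higher. Values close to this were found in myeloid-like (0.46), smooth muscle-like (0.42), fibroblast-like (0.42) and endothelial-like nuclei (0.41). Over all named nuclei together, only cardiomyocyte-like nuclei had a median below 0, at -0.76.

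Heat shock genes were highest in fibroblast-like nuclei over all named nuclei together, with a median of 1.56 (12 of 16 higher). They were led by HSPA1B (1768 CPM, 6.12-fold), HSPH1 and DNAJB1. Neuronal or glial-like nuclei had a median of 1.45. The unnamed cluster led by FOSB and ATF3, left out here, had HSPA1B and HSPA1A among its top 10 genes. Without the 4 clusters HSPA1B was 1.33-fold, HSPH1 0.729-fold and DNAJB1 0.908-fold. HSPA1B is nearly identical to HSPA1A, and its level is uncertain to that extent. The order was the opposite within barcode sets: the median was -0.56 in fibroblast-like nuclei, above 0 in 3 of 15 sets, and 0.59 in cardiomyocyte-like nuclei, above 0 in 10 of 13 sets, where the pooled value was -1.47. Without the 4 clusters found in few sets the medians were -0.25 in fibroblast-like and -0.41 in cardiomyocyte-like nuclei, and highest, at 2.11, in neuronal or glial-like nuclei, so the order within sets was not kept there.

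**Figure D4:**
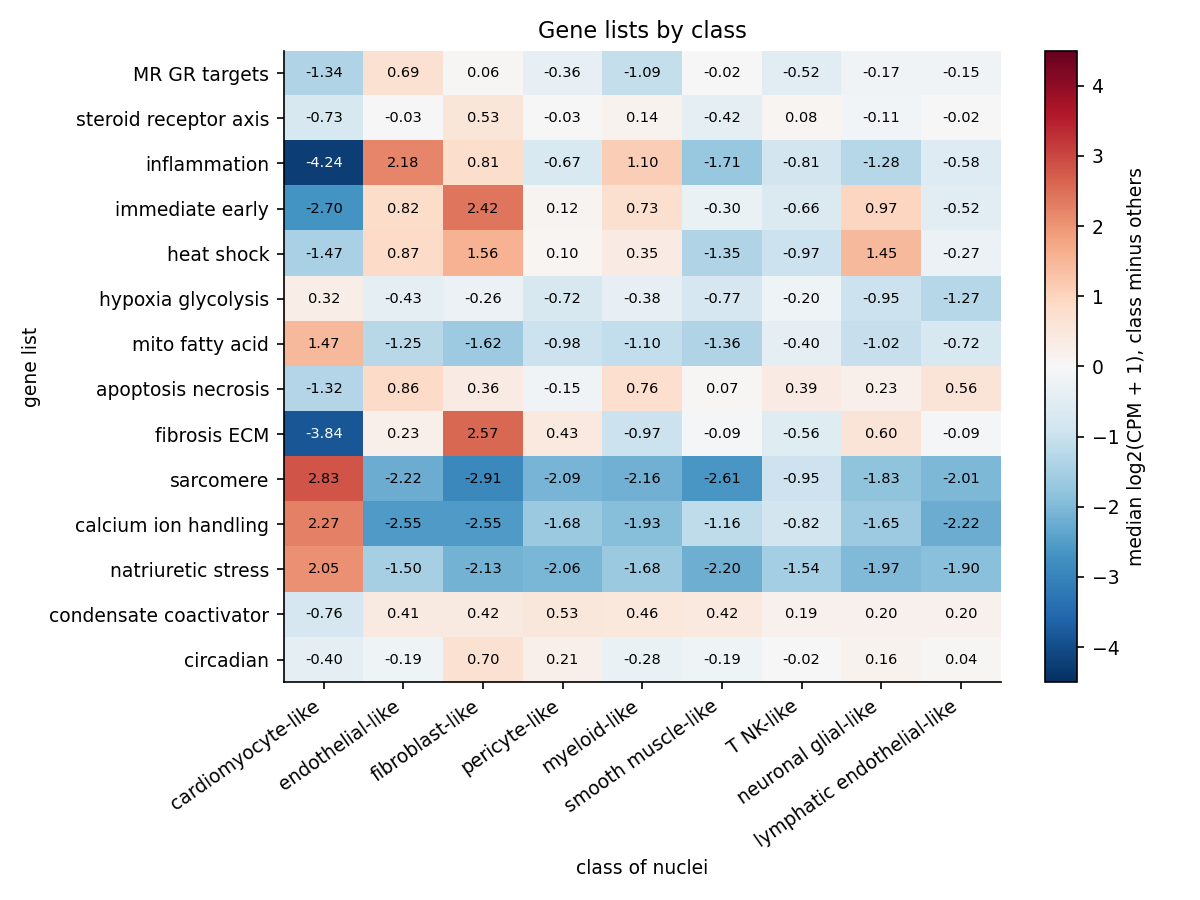
Median over the measured genes of each list (vertical) of the log2 difference in CPM, with a pseudocount of 1, between classes of nuclei. Each class (horizontal) is set against all the other named classes, over all named nuclei together. Sarcomere genes in cardiomyocyte-like nuclei (2.83) are the highest cell and inflammation genes in cardiomyocyte-like nuclei (-4.24) the lowest.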

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

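The explanations weighed and their bounds, the overlap of the strongest 10% of peaks, the thinning and the ratio of peak numbers away from gene ends were chosen only after the results were seen, whereas the values at a -log10 q of 5 or more and the overlap of whole lists were planned. The measures below went in opposite directions in the 2 solutions or at the 2 times, with 1 library per group, and none of these differences was tested against replicates.

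From baseline to 10 h, the share of peaks at gene ends differed by -4.63 percentage points in HTK and by 8.03 points in HTK+CAN. The share outside protein-coding genes differed by 11.0 points in HTK and by -6.21 points in HTK+CAN. The ratio of median expression between genes with and without a gene-end peak differed by -0.74 in HTK and by 0.60 in HTK+CAN. The number of peaks in HTK+CAN relative to HTK was 6.61 at baseline and 0.330 at 10 h.

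The first pattern weighed is the longer peak list of HTK+CAN at baseline. Receptor signal at more gene ends is argued against as the whole cause, since among peaks over 3 kb from a gene end that list was still 9.34 times as long as the HTK list. The number of measured genes reached does not decide it, at 0.640 times the HTK number within 1 kb and 1.26 times within 3 kb. Low effective depth with peaks called at few fragments fits the ratio of peak numbers at a -log10 q of 5 or more, which was 0.225, below 1. A low background did not always go with a long list. The HTK+CAN list at 10 h had a like background (0.180 against 0.183 fragments) and 1809 peaks, with at least 6 fragments at the recovered summits. Another control in the peak calling also stays open, since the HTK+CAN lists do not name theirs. More receptor sites away from gene ends cannot be told apart from low depth. The 2.93% of HTK+CAN peaks at 10 h that overlapped the baseline list come from a short list at another storage time.

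The second pattern is the gene-end share, lower at 10 h in HTK and higher at 10 h in HTK+CAN. At a -log10 q of 5 or more the HTK+CAN share at 10 h was still 5.07 times that at baseline. This argues against the peaks below that threshold as the whole cause. It does not decide on weak peaks in general, because the 1321 HTK+CAN baseline peaks above the threshold include peaks of few fragments. The gene-end peaks of CXCL2 and GADD45B, for example, passed it with 7 and 8 fragments at the summit. Another placing of the receptor in the HTK+CAN heart at baseline stays open. The HTK baseline list overlapped the HTK+CAN baseline list 1.86 times as often as random positions, and a library of low signal or another control in the peak calling could give the same value.

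The third pattern is the shorter HTK list at 10 h. A lower effective depth stays open as the cause. Of the strongest 10% of baseline peaks, 68.1% (65.1 to 70.9) overlapped the 10 h list, and 73.9% (70.0 to 77.5) of the strongest 10% of peaks at 10 h overlapped the baseline list, so strong peaks differed in both directions. Thinning the recovered baseline fragments until 5485 peaks were left would keep 99.0% of the strongest 10%, which is more than overlapped in either direction. The intervals of the 2 shares meet, so a loss of strong peaks beyond what differs in both directions is not shown. The recovered background was 0.815 times that at baseline. The thinning keeps 0.351 of the fragments with the background lowered alike, and 0.548 with the background at that ratio. Different peak positions in 2 libraries do not show why 1 list is shorter. A change of receptor signal during storage in HTK may contribute. It cannot be told apart from depth or from a difference between 2 libraries or hearts, since no group had a replicate.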

How the results depend on the processing

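The thresholds of -log10 q of 2 and 3, the values within or weighted by barcode sets and the omission of 4 clusters found in few sets were chosen after seeing the data, and the other alternatives before. Over the results that answer a comparison, 61 of 110 alternatives gave the same value within its interval or within 1.5 times, 48 moved it and 1 reversed it. Among single genes and lists, 238 of 317 were the same, 77 moved and 2 reversed. The ratio of peak numbers in HTK between 10 h and baseline stayed within 1.5 times under every alternative run. The ratio of expression between genes with and without a peak stayed within 1.5 times in all 4 lists under each alternative. Except where stated, the cause of a shift was not tested.

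Peak numbers depended on the threshold wherever HTK+CAN was involved. The ratio of HTK+CAN at 10 h to baseline was 0.184 at a -log10 q of 5, 0.0930 at 3, 0.0635 at 2 and 0.112 at a fold of 5. HTK+CAN over HTK at baseline reversed to 0.225 at a -log10 q of 5, and was 1.24 at 3, 2.79 at 2 and 1.74 at a fold of 5. At 10 h this ratio was 0.0854 at 5 and 0.219 at 3.

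Shared peaks are given for a reciprocal overlap of 50%, summits within 200 bp, the top 1809 peaks of each list, and a -log10 q of 5, in that order. HTK at 10 h in HTK at baseline was 36.3%, 41.4%, 36.4% and 51.4%. HTK baseline in HTK+CAN baseline was 1.60%, 2.11%, 0.387% and 0.221%. HTK+CAN at 10 h in HTK at 10 h was 2.16%, 1.99%, 1.49% and 7.82%. HTK+CAN at 10 h in HTK+CAN baseline was 1.44%, 1.55%, 0.663% and 3.70%, the last within the interval of the main value. Stricter overlap lowers these shares by construction.

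The gene-end share at 3 kb, at a -log10 q of 5 and in the top 1809 peaks was 34.4%, 29.97% and 36.1% in HTK at baseline and 28.6%, 25.7% and 28.1% in HTK at 10 h. It was 7.37%, 5.60% and 4.75% in HTK+CAN at baseline. In HTK+CAN at 10 h it was 16.7% at 3 kb and 28.4% at a -log10 q of 5. The number of lists at or above the 95th percentile was 2 in HTK at baseline, and 5 at 3 kb and 11 with lists matched on gene length. With length matching it was 7 in HTK at 10 h, against 2, and 2 in HTK+CAN at baseline, against 1.

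Among nuclei, endothelial-like nuclei were 22.1% at 500 genes and 20.8% without doublet removal. At resolution 1.0, pericyte-like nuclei were 8.31%, myeloid-like 8.64% and unnamed 7.61%. Smooth muscle-like nuclei were 2.57% without doublet removal, and T or NK cell-like nuclei 0.972% at 500 genes. Unnamed nuclei were 19.1% at 500 genes, where no cluster met the naming rule for pericytes, and 9.11% without doublet removal. The heat shock median in fibroblast-like nuclei reversed to -0.56 within barcode sets and to -0.25 without the 4 clusters found in few sets. Without those clusters the pooled direction was lost, so they set it.

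No alternative of the hormone response element share was run. No paired analysis was possible because each group had 1 library. The read totals that would show the depth of each list are not in the sources used here. The median peak had 3 fragments at the summit in the HTK+CAN baseline list and 16 in both HTK lists.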

Other observations

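All values in this part were chosen after seeing the data, and no test was made on them. Several stress and inflammatory clusters each lay almost wholly in 3 of the 15 barcode sets. They were the fibroblast-like cluster led by LIF, INHBA and PTX3, the endothelial-like cluster led by SELE and CSF3, the pericyte-like cluster led by MUC3A and ADAMTS4, and the myeloid-like cluster led by IL1B. Unnamed clusters led by FOSB and ATF3 and by SGMS2 and KLHL41 were spread in the same way. The LIF cluster made up 13.4% to 31.6% of nuclei in 3 sets and at most 0.267% in the other 12. The SELE cluster made up 12.1% to 19.4% in 3 sets and at most 0.401% elsewhere. Over the 15 sets, IL6 in endothelial-like nuclei ranged from 6.71 to 10133 CPM with a median of 46.5, and SELE from 3.61 to 11018 CPM with a median of 13.7. CXCL8 in fibroblast-like nuclei ranged from 0 to 5243 CPM and IL1B in myeloid-like nuclei from 0 to 2034 CPM, both with a median of 0. No label ties a set to a heart, solution, time or processing step, so these values cannot be assigned to storage.

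Corticosteroid target genes varied between sets in cardiomyocyte-like nuclei as well, over the 13 sets with at least 20 such nuclei. PDK4 ranged from 36.6 to 4416 CPM with a median of 455, ZBTB16 from 213 to 770 CPM with a median of 387 and FKBP5 from 63.4 to 239 CPM with a median of 102. NR3C2 ranged from 46.5 to 260 CPM with a median of 68.3. The natriuretic peptide genes NPPA and NPPB ranged from 2.82 to 786 CPM and from 0 to 1084 CPM. The share of cardiomyocyte-like nuclei ranged from 0% to 55.3% with a median of 23.9%.

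In the HTK+CAN baseline list, 43.2% of peaks (28745) carried the same pair of fold and -log10 p, and in the HTK+CAN list at 10 h 36.3% (656) did. In the HTK lists the commonest pair was shared by 2.36% of peaks at baseline and 3.06% at 10 h.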
